A study of Mus musculus with 16 samples.

How the data were processed

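Total RNA of whole mouse lung was labelled as biotinylated sense-strand DNA from 50 ng of RNA and hybridised to 16 Affymetrix whole-transcript arrays, 4 per group, per the labels' protocols. The groups were wild-type (WT) mice given saline, WT mice given house dust mite extract (HDM), and Vldlr knockout (KO) mice given either. The deposited values are on the log2 scale, with 1 value per probe set and array. They were made with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, normalizes across arrays and summarises the probes of a probe set, so levels of different probe sets are not comparable with each other. The versions of these tools and the genome build behind the array annotation are not given in the sources used here. Scanner files were not used here. The number of arrays limits the precision of every value.

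The table held 35556 probe sets. The platform annotation gave 1 gene symbol for 21789 of them and several for 1621, and 12146 were not named. Of those with 1 symbol, 21698 matched a gene of the GRCm38.p6 reference table by gene ID and 91 did not and kept their name, and 0 symbols were updated. That table was used for names and for which genes lie near each other, and no coordinates are given. Only probe sets with 1 symbol were used, and for the 999 genes with several of them the probe set with the highest mean over the 16 arrays was kept, which left 19938 genes. No filter on dim genes was applied in the main analysis. All 16 arrays had Xist above 12 and Y-linked genes below 8 (levels chosen after the values were seen).

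The values were fitted as deposited, with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), 4 group means, no covariate and 12 residual degrees of freedom. The 5 comparisons were HDM against saline in each genotype, knockout against wild type under each treatment, and the interaction, which is the HDM change in the knockout minus that in wild type. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and a gene passed at an adjusted p under 0.05. Tests were two-sided. SE is limma's standard error of the log2 change, and SD the spread between the arrays of a group. The comparisons of HDM with saline share no array with each other, and neither do those of genotype. Overlaps of calls were set beside the number that independent lists of the same lengths would give.

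Before the data were examined, 39 gene lists with 516 members were fixed, of which 473 were measured, and genes within 10 Mb of Vldlr were added as a further list, making 40. The fixed lists covered type 2 cytokines, type 2 and other chemokines, interferon response, type 17 cytokines, acute phase, mucous cells, alternative macrophage activation, MHC class II, matrix, proliferation, lipoprotein receptors, cholesterol synthesis, LXR targets, clock, immediate early genes, sex, and cell types. The cell types were eosinophils, mast cells and basophils, T, B, plasma, NK and dendritic cells, neutrophils, alveolar macrophages, monocytes and interstitial macrophages, alveolar type 1 and 2, club, ciliated and endothelial cells, smooth, cardiac and skeletal muscle, adipose tissue, squamous and tracheal epithelium, thymus and thyroid, and erythroid cells. Lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01. P-values were adjusted over the lists of a comparison, and the test was repeated with the correlation estimated from the data. The fry test, which asks whether the genes of a list move on balance in one direction, stands beside it. Some genes belong to several lists, for example Ccr3 and Il5ra to the eosinophil list and to a type 2 list. The MHC class II list also held other antigen presentation genes, such as Cd86.

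Also fixed before the data were examined were the main tests, the alternatives and the rule for named genes. That rule took Vldlr first, then per comparison the 12 largest rises and falls (10 each for the interaction) among genes that passed and whose groups did not overlap (for the interaction, that passed), without predicted genes, small RNAs and immunoglobulin or T cell receptor segments. If fewer than 5 genes passed, it took the 5 with the smallest p. It added up to 4 members of each list per comparison, the largest changes among those that passed, filled to 2 by the smallest p, and allowed Apoe, Lrp8, Ccl17, Ccl22, Ccl24 and Ccl11 everywhere, and a further gene that is not reported here. The subset named in the text was chosen after the values were seen.

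The alternatives were quantile normalization, a shift of arrays to the same median, filters at the 25th and 50th percentile of expression, a variance trend with robust estimation, array weights, a fit of only the 2 groups compared, the mean of a gene's probe sets, the replicate number as a block, an estimated correlation for the lists, an added 2-fold threshold, all probe sets, and leaving out each array. The planned covariate for sex, meant for arrays of both sexes, was not run, as all 16 arrays had high Xist and low Y-linked signal. A clock score (the mean of Dbp, Tef, Hlf, Per2, Per3, Nr1d1, Nr1d2 and Ciart minus Arntl) as a covariate, the fry test and leaving out WT saline 2 and 3 together were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures. The procedure was tested on simulated data (200 of 19938 genes changed), whose rates may not hold here. Log2 changes of 1 were recovered in 95.52% (interaction) to 100% of cases and changes of 0.5 in 62.69% (interaction) to 91.04% (genotype under saline). Changes of 2 were recovered in 96.97% (HDM in wild type, genotype under HDM and interaction) to 100% (HDM in the knockout), and false calls made up 4.49% to 6.03% of calls.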

Results

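Gene expression in whole lung was measured on 16 Affymetrix whole-transcript arrays, 4 for each combination of genotype and treatment. The mice were wild type (WT, B6129SF2/J) or carried a targeted disruption of Vldlr (KO), the gene of the very low density lipoprotein receptor, a membrane protein that binds apolipoprotein E and other ligands. Both genotypes received either saline or house dust mite extract (HDM), an inhaled allergen used to produce asthma-like airway inflammation in mice, through the nose. A dose held 25 µg of HDM in 10 µl and was given on 5 days of each week for 6 weeks. The arrays of a group were described as biological replicates, without the number of animals behind each RNA sample, so p-values measure the spread between these samples. Levels and changes are on the log2 scale, and arrays are named by group and replicate number. Values on all arrays lay between 3.05 and 14.7, array medians between 8.78 and 8.85, and correlations between arrays between 0.9798 and 0.9972. The first principal component held 34.1% of the variance, with saline arrays between -16.42 and -6.69 and HDM arrays between -0.06 and 23.83. The second held 21.4%. On it KO HDM 1, 2 and 3 lay at 16.1, 8.35 and 11.05, the WT HDM arrays between -27.1 and -8.75, and KO HDM 4 at -3.26.

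Vldlr itself was lower on all 8 KO arrays than on all 8 WT arrays. Its level was 10.54, 10.50, 10.59 and 10.75 on WT saline arrays 1 to 4, and 10.56, 10.92, 10.48 and 10.27 on the WT HDM arrays. On KO saline arrays 1 to 4 it was 9.88, 9.77, 9.90 and 9.79, and on the KO HDM arrays 9.57, 9.62, 9.40 and 9.91. The difference between genotypes was -0.76 under saline (SE 0.12, n = 4 per group, limma adjusted p = 0.00697) and -0.93 under HDM (SE 0.12, adjusted p = 0.000277). With WT saline 2 and 3 left out the difference under saline was -0.81 and did not pass. With a clock score as a covariate, chosen after the data were seen, the difference under HDM was -0.75 (SE 0.21, adjusted p = 0.325). A signal remained on the KO arrays. Which part of the gene was disrupted, and where the probes lie relative to it, is not given in the sources used here.

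**Figure D1:**
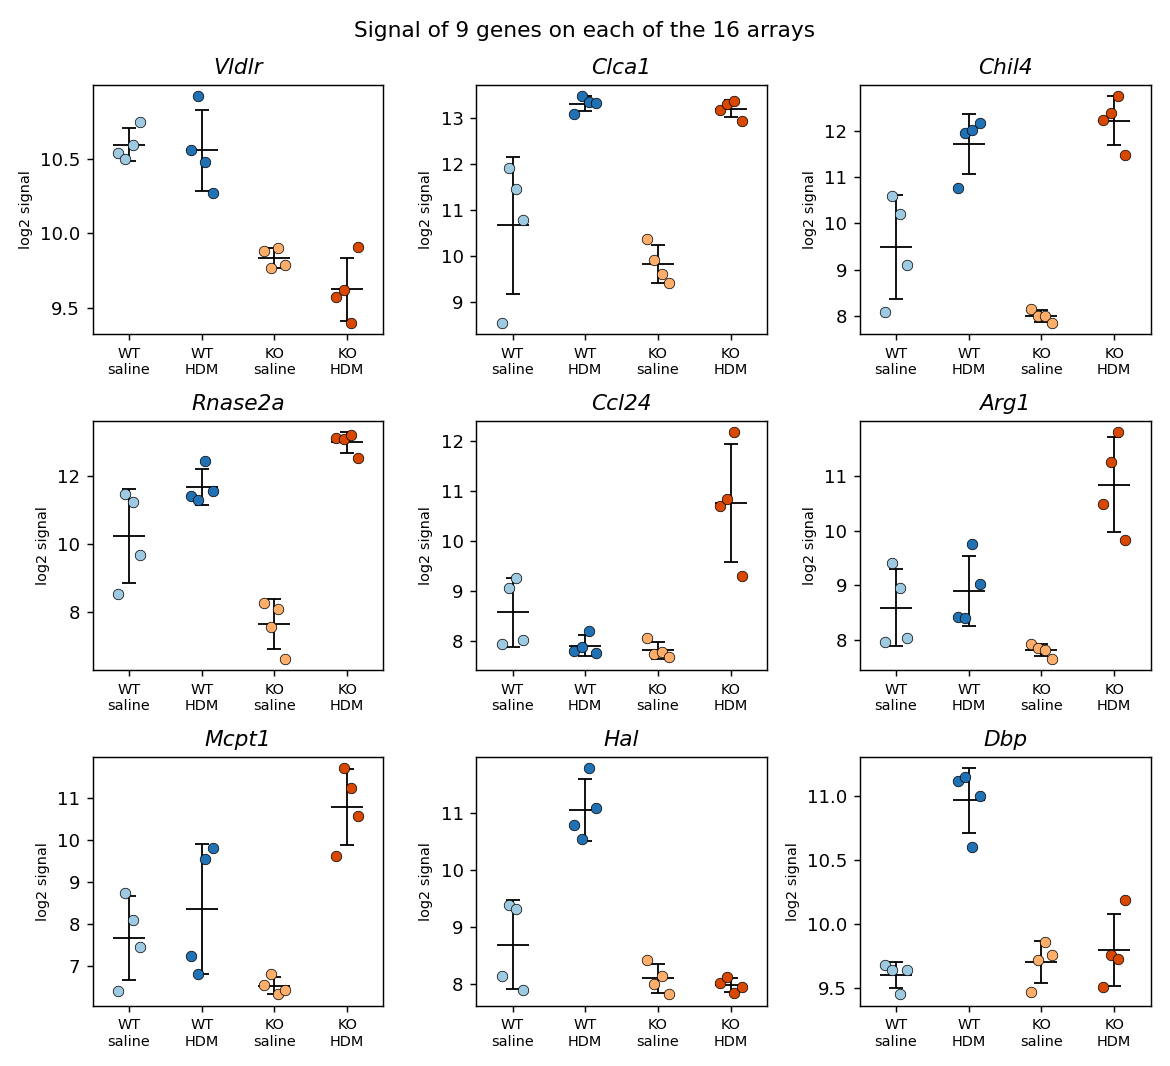
Log2 level of 9 genes (Vldlr, Clca1, Chil4, Rnase2a, Ccl24, Arg1, Mcpt1, Hal and Dbp) on each of the 16 arrays, with points for arrays, bars for the group mean and SD (n = 4), and axes that do not start at 0. Ccl24 lies between 9.30 and 12.18 in the KO HDM group and between 7.76 and 8.21 in the WT HDM group, while Hal lies between 10.55 and 11.79 in the WT HDM group and between 7.84 and 8.12 in the KO HDM group.

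The comparison of HDM with saline in WT mice asked what the allergen did to lungs that had the receptor. Genes of mucous cells, eosinophils and alternatively activated macrophages were among those that rose most. Clca1, a secreted protein of goblet cells, rose by 2.64 (SE 0.46, 6.22-fold, n = 4 per group, limma adjusted p = 0.00193), from 10.68 ± 1.49 (SD) to 13.31 ± 0.16. Chil4, a chitinase-like protein of airway epithelium and macrophages, rose 4.7-fold (SE 0.42 on the log2 scale, adjusted p = 0.00282), and Ccr3, the eotaxin receptor of eosinophils, 3.44-fold (SE 0.18, adjusted p = 4.45e-05). Glycam1, an L-selectin ligand of high endothelial venules, fell by 2.37 (SE 0.26, adjusted p = 7.88e-05), and the neutrophil attractant Cxcl5 fell by 1.55 (SE 0.12, adjusted p = 3.24e-06).

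Of 14 measured mucous cell genes 7 rose and none fell (7 and 0 adjusted over the list alone), among them the gel-forming mucin Muc5ac (1.42), its folding helper Agr2 (1.18) and the anion exchanger Slc26a4 (1.0). The list was higher by camera (median 0.39, adjusted p = 0.000192, adjusted p = 0.158 with an estimated correlation). Of 16 genes of alternative macrophage activation 7 rose and none fell (9 and 0 adjusted over the list alone), with Chil3 up by 1.26 and the elastase Mmp12 by 1.51, at an adjusted p = 3.97e-05 for the list and an adjusted p = 0.43 with an estimated correlation. In the eosinophil list 3 of 8 genes rose (3 adjusted over the list alone), which were Ccr3, Alox15 (1.68) and the interleukin receptor chain Il5ra (1.30). Its adjusted p = 0.00227, and adjusted p = 0.43 with an estimated correlation. Type 2 chemokines and their receptors rose in 3 of 10 cases (3 adjusted over the list alone), with the eosinophil attractant Ccl11 up by 1.01 and the T cell attractant Ccl17 by 0.94 (list median 0.088, adjusted p = 0.0381, adjusted p = 0.632 with an estimated correlation). Ccl24, a second eotaxin, was at 7.91 ± 0.20 under HDM and 8.58 ± 0.68 under saline and did not pass (-0.66, adjusted p = 0.25), nor did Ccl22 (0.29, adjusted p = 0.244). Among 15 type 2 cytokines and receptors 2 rose and 1 fell (2 and 1 adjusted over the list alone). Il33, an epithelial alarm cytokine, rose by 0.49, Il25 fell by 0.22, and the list did not pass (adjusted p = 0.471).

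Dendritic cell genes rose in 4 of 16 cases and fell in 1 (5 and 1 adjusted over the list alone, adjusted p = 0.00512, adjusted p = 0.43 with an estimated correlation), with the integrin Itgax up by 1.16. Monocyte and interstitial macrophage genes rose in 4 of 10 (6 and 1 lower adjusted over the list alone), for example the complement gene C1qb by 0.72, at an adjusted p = 0.00197 and an adjusted p = 0.43 with an estimated correlation. Plasma cell genes had a median of 0.32 with no member past the test (0 adjusted over the list alone, adjusted p = 0.0053, adjusted p = 0.602 with an estimated correlation). Of 10 NK cell genes 3 fell (5 adjusted over the list alone), where Nkg7 fell by 0.62 and Gzma fell by 0.75 (list adjusted p = 0.0308, adjusted p = 0.637 with an estimated correlation). In 11 alveolar type 2 cell genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), the surfactant protein Sftpd by 0.59 and Lamp3 by 0.45 (adjusted p = 0.00773, adjusted p = 0.43 with an estimated correlation). The alveolar type 1 list did not pass (adjusted p = 0.12), although Aqp5 fell by 0.54 and Rtkn2 fell by 0.52. Skeletal muscle genes, markers of tissue outside the lung, fell in 2 of 8 cases (5 adjusted over the list alone, adjusted p = 0.0153, adjusted p = 0.43 with an estimated correlation).

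Of 19 lipoprotein receptors and ligands 5 rose (5 and 2 lower adjusted over the list alone, list adjusted p = 0.12). Apoe, a ligand of the deleted receptor, rose by 0.25 (SE 0.08, adjusted p = 0.0488), and Lrp8, its closest relative, did not pass (-0.11, adjusted p = 0.25). Targets of the sterol-sensing LXR receptors and fatty acid synthesis genes rose in 3 of 14 cases (4 adjusted over the list alone, adjusted p = 0.000514, adjusted p = 0.43 with an estimated correlation), among them the lipid exporter Abcg1 (0.37). Circadian clock genes moved with these groups on the same arrays. Of 14, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with Dbp up by 1.37 (SE 0.13, adjusted p = 3.54e-05), Bhlhe41 by 1.32, Per3 by 0.63 and Tef by 0.60 (list adjusted p = 3.97e-05, adjusted p = 0.43 with an estimated correlation).

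In all, 3505 of 19938 genes changed in WT lungs, 1568 higher and 1937 lower, with 51 changed at least 2-fold and a median size of 0.275. Higher calls made up 44.7%, and 56.3% (1668 higher, 1296 lower) when arrays were shifted to the same median. WT saline 2 and 3 stood apart from the other saline arrays, with Rnase2a, an eosinophil-associated ribonuclease on the alternative macrophage list, at 11.47 and 11.22 against 8.54 and 9.68 on WT saline 1 and 4. Without both, with fewer arrays, 1057 genes changed (646 higher, 411 lower) and 9 of 48 single-gene calls ended, that of Apoe among them. Clca1 (3.6), Chil4 (3.1), Ccr3 (2.0) and Cxcl5 (-1.7) then changed more and Glycam1 (-2.2) less. With the clock score as a covariate, which widened the median SE 2.12 times, 43 genes passed, and Clca1 (3.87, SE 0.94) and Chil4 (3.32, SE 0.85) did not. The count was 1969, 2141 and 2209 without WT saline 1, 2 and 3, and 2277 and 1960 without WT HDM 2 and 4. Of 48 single-gene calls examined, 6 ended without WT HDM 4, 5 without each of WT HDM 2, WT saline 1 and WT saline 2, 4 without WT saline 3, 3 without WT HDM 3 and at most 2 without any other array. Of the 12 list calls, 2 ended without each of WT saline 4 and WT HDM 3, and 1 without each of WT saline 1, WT saline 3, WT HDM 1 and WT HDM 4. The median, mean and test differed in sign for the type 2 cytokine, matrix, cholesterol synthesis, immediate early, T cell, alveolar macrophage, club cell, adipose and Vldlr-flanking lists, none of which passed.

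The same comparison in KO mice asked what HDM did without the receptor. Genes of mast cells, alternatively activated macrophages and eosinophil attraction were among the largest rises. Rnase2a rose 40.4-fold (5.33, SE 0.49, n = 4 per group, limma adjusted p = 5.4e-06), from 7.63 ± 0.74 (SD) to 12.97 ± 0.30. The mast cell proteases Mcpt1 and Mcpt2 rose 18.9-fold (SE 0.61, adjusted p = 0.000327) and 24.7-fold (SE 0.60, adjusted p = 0.000139). Chil4 rose 18.7-fold (SE 0.42, adjusted p = 9.09e-06), Arg1, the arginine-degrading enzyme of alternatively activated macrophages, 8.1-fold (SE 0.38, adjusted p = 0.000106), and Ccl24 7.69-fold (SE 0.41, adjusted p = 0.000261). Glycam1 fell by 1.88 (SE 0.26, adjusted p = 0.000235) and the cytokine gene Il18 fell by 1.57 (SE 0.21, adjusted p = 0.000222).

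With an estimated correlation 5 lists were higher. Of 10 type 2 chemokines and receptors 7 rose (8 adjusted over the list alone), with Ccl11 up by 2.18, Ccr3 by 2.60, Ccl8 by 1.58 and Ccl22 by 1.0 (list median 0.99, adjusted p = 2.26e-13, adjusted p = 0.025 with an estimated correlation). In the alternative macrophage list 13 of 16 rose (13 and 1 lower adjusted over the list alone), with Mmp12 up by 3.44 (adjusted p = 2.86e-16, adjusted p = 0.025 with an estimated correlation). Eosinophil genes rose in 6 of 8 cases (7 adjusted over the list alone), with Alox15 up by 2.91, Il5ra by 1.71 and the ribonuclease Ear6 by 1.41 (adjusted p = 3.14e-12, adjusted p = 0.025 with an estimated correlation). Of 14 mucous cell genes 6 rose (8 adjusted over the list alone), with Clca1 up by 3.38, Slc26a4 by 1.91, Muc5ac by 1.23 and the lectin Itln1 by 1.13 (adjusted p = 6.24e-09, adjusted p = 0.0116 with an estimated correlation). Of 20 matrix genes 11 rose and 1 fell (14 and 1 adjusted over the list alone), with the protease inhibitor Timp1 up by 1.78, tenascin C (Tnc) by 0.85 and Mmp14 by 0.57 (adjusted p = 5.28e-10, adjusted p = 0.0161 with an estimated correlation).

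Other immune lists passed by the preset correlation alone. Type 2 cytokines and receptors rose in 7 of 15 (9 and 1 lower adjusted over the list alone), with the decoy receptor Il13ra2 up by 1.17, Il33 by 0.63 and Il10 by 0.53 (adjusted p = 3.78e-05, adjusted p = 0.116 with an estimated correlation). Mast cell and basophil genes rose in 6 of 14 (7 and 1 lower adjusted over the list alone), among them Cpa3 by 1.59 (adjusted p = 0.000184, adjusted p = 0.239 with an estimated correlation). Dendritic cell genes rose in 7 of 16 (9 adjusted over the list alone), with Cd209e up by 2.36 and Itgax by 1.61 (adjusted p = 5.76e-08, adjusted p = 0.0764 with an estimated correlation). In the monocyte and interstitial macrophage list 6 of 10 rose and 1 fell (8 and 1 adjusted over the list alone), with Ms4a7 up by 1.35 and C1qa by 0.67 (adjusted p = 4.28e-05, adjusted p = 0.239 with an estimated correlation). MHC class II genes rose in 2 of 11 (2 adjusted over the list alone, adjusted p = 0.00987, adjusted p = 0.469 with an estimated correlation). Proliferation genes rose in 1 of 22 (1 adjusted over the list alone, adjusted p = 0.00127, adjusted p = 0.516 with an estimated correlation). Plasma cell genes rose in none of 11 (3 adjusted over the list alone, adjusted p = 0.0402, adjusted p = 0.516 with an estimated correlation). In the NK cell list 1 of 10 fell (6 adjusted over the list alone), Klrd1, which fell by 0.55 (adjusted p = 0.00265, adjusted p = 0.398 with an estimated correlation).

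In the club cell list 6 of 11 fell (6 adjusted over the list alone), with the secretoglobin Scgb3a2 at -1.05 and the cytochrome Cyp2f2 at -0.43 (adjusted p = 3.78e-05, adjusted p = 0.116 with an estimated correlation). In the ciliated cell list 5 of 13 fell (11 adjusted over the list alone), with Tppp3 at -0.73 and the dynein Dnah5 at -0.40 (adjusted p = 6.49e-06, adjusted p = 0.239 with an estimated correlation). Alveolar type 1 genes fell in 6 of 10 (7 adjusted over the list alone), with Aqp5 at -0.59, Rtkn2 at -0.46 and Hopx at -0.38 (adjusted p = 2.23e-05, adjusted p = 0.257 with an estimated correlation). Alveolar type 2 genes fell in 1 of 11 (3 adjusted over the list alone, adjusted p = 0.00704, adjusted p = 0.306 with an estimated correlation). Endothelial genes rose in 1 of 14 and fell in 3 (1 and 5 adjusted over the list alone), with Vwf at 0.48 and Tmem100 at -0.66 (adjusted p = 0.00673 for a lower list, adjusted p = 0.469 with an estimated correlation). Squamous and tracheal epithelium genes fell in 2 of 8 (2 adjusted over the list alone, adjusted p = 0.0363, adjusted p = 0.312 with an estimated correlation). Smooth muscle genes rose in 5 of 10 (5 adjusted over the list alone), with Acta2 at 0.43 and Myh11 at 0.54 (adjusted p = 6.49e-06, adjusted p = 0.218 with an estimated correlation). Further tissue lists moved too. Adipose genes fell in 2 of 7 (3 adjusted over the list alone), with Cidec at -0.74 (adjusted p = 0.0016, adjusted p = 0.257 with an estimated correlation). Cidec is also on the alveolar macrophage list, so its fall does not tell these tissues apart. Cardiac muscle genes had a median of -0.35 with none past the test (0 adjusted over the list alone, adjusted p = 0.016, adjusted p = 0.469 with an estimated correlation).

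Altogether 1763 genes changed in KO lungs, 989 higher and 774 lower, with 121 changed at least 2-fold and a median size of 0.370. Apoe (0.02, adjusted p = 0.897), Lrp8 (0.05, adjusted p = 0.73) and the lipoprotein list (2 of 19 higher, 1 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.183) did not pass. Nor did the clock list (1 of 14 higher, 0 adjusted over the list alone, adjusted p = 0.607), in which Bhlhe41 rose by 0.53. The count was 1055 without KO saline 2, and 1158, 1034 and 2673 without KO HDM 1, 3 and 4. Of 70 single-gene calls examined, 5 ended without KO saline 1, 4 without each of KO saline 2, KO saline 4 and KO HDM 3, 3 without each of KO saline 3, KO HDM 1 and KO HDM 2, and at most 2 without any other array. Of 22 list calls, 5 ended without KO HDM 1, 3 without KO saline 2, 2 without KO HDM 3, and 1 without each of KO saline 4, KO HDM 2 and KO HDM 4. The median, mean and test differed in sign for the other chemokine, type 17, LXR, immediate early, thymus and thyroid, and Vldlr-flanking lists, none of which passed.

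The 2 HDM comparisons share no array. In both, 424 genes were higher, against 77.78 for independent lists of these lengths, and 216 were lower, against 75.2. A further 19 genes changed in opposite directions. Higher genes made up 66.2% of those changed the same way, and 55.7% (369 higher, 294 lower) after quantile normalization. Without KO saline 2 the genes changed the same way numbered 419, without WT saline 2 and 3 they numbered 320, and in the full data 640. The clock score as a covariate left 37. Across genes, which are not independent replicates, the correlation of the changes was 0.505 (Pearson) and 0.408 (Spearman).

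**Figure D2:**
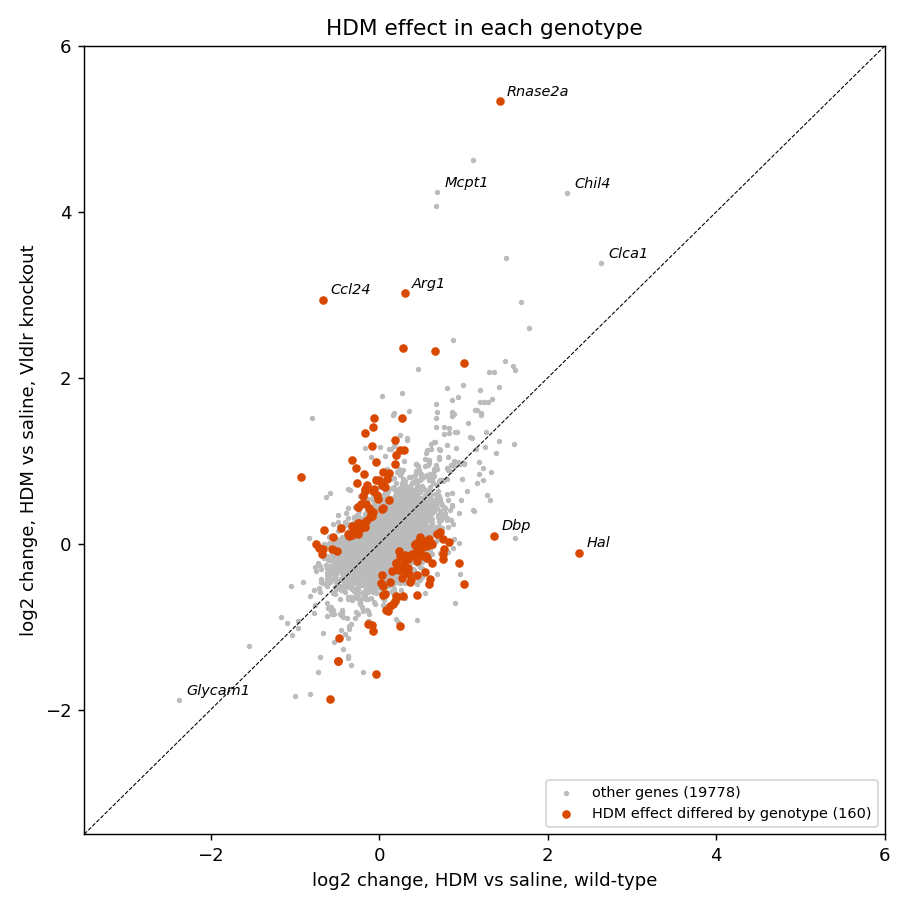
Log2 change with HDM in WT lungs (horizontal axis) and in KO lungs (vertical axis), 1 point per gene, with the 160 genes of different HDM effect coloured, all others in grey and a dashed line where both changes are equal. Rnase2a (1.43 in WT, 5.33 in KO) and Ccl24 (-0.66 and 2.94) lie far above the line, and Hal (2.37 and -0.11) far below it.

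Whether the HDM effect differed by genotype was tested directly, as the change in KO minus the change in WT. Among genes that passed, the chemokine Ccl24 and the alternative macrophage genes Rnase2a and Arg1 had the largest positive differences. For Rnase2a the difference was 3.90 (SE 0.70, n = 4 per group, limma adjusted p = 0.0182), for Ccl24 3.61 (SE 0.58, adjusted p = 0.01) and for Arg1 2.71 (SE 0.54, adjusted p = 0.0289). Hal, the histidine-degrading enzyme, showed the largest negative difference, -2.48 (SE 0.42, adjusted p = 0.0126) between a change of 2.37 in WT and of -0.11 in KO. Differences of 3.55 for Mcpt1 (adjusted p = 0.0588), 3.52 for Mcpt2 (adjusted p = 0.0583), 1.16 for Il13ra2 (adjusted p = 0.0624) and 0.04 for Ccl17 (adjusted p = 0.954) did not pass.

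Type 2 chemokines and receptors had a more positive change in KO in 3 of 10 cases (6 adjusted over the list alone), with Ccl11 at 1.17 and Ccr8, a receptor of type 2 T cells, at 1.02 (list median 0.78, adjusted p = 5.33e-07, adjusted p = 0.146 with an estimated correlation). On WT saline arrays 1 to 4, which enter this difference, Ccl24 was at 7.95, 9.07, 9.26 and 8.03 and Arg1 at 7.97, 9.41, 8.96 and 8.05. Eosinophil genes differed in this direction in 2 of 8 (5 adjusted over the list alone), Ear6 at 1.48 and Cebpe at 0.62 (adjusted p = 4.61e-05, adjusted p = 0.209 with an estimated correlation). Alternative macrophage genes differed in the same direction in 2 of 16 (7 adjusted over the list alone, adjusted p = 0.000124, adjusted p = 0.301 with an estimated correlation). Of 20 matrix genes 4 had a positive and 1 a negative difference (13 and 2 adjusted over the list alone), with Tnc at 1.02, elastin (Eln) at 0.69, Col3a1 at 0.43 and decorin (Dcn) at -0.56 (adjusted p = 3.88e-07, adjusted p = 0.11 with an estimated correlation). Type 2 cytokines and receptors were higher as a list (none of 15, 2 adjusted over the list alone, adjusted p = 0.00242, adjusted p = 0.253 with an estimated correlation). Proliferation genes (none of 22, 0 adjusted over the list alone, adjusted p = 3.97e-05, adjusted p = 0.557 with an estimated correlation) and mast cell genes (none of 14, 2 adjusted over the list alone, adjusted p = 0.0186, adjusted p = 0.557 with an estimated correlation) were higher as lists too. So were smooth muscle genes (none of 10, 3 adjusted over the list alone, adjusted p = 0.0131, adjusted p = 0.557 with an estimated correlation) and dendritic cell genes. In the dendritic list Cd209e was at 2.07, Clec9a at -0.57 (1 higher and 1 lower of 16, 1 and 1 adjusted over the list alone, adjusted p = 0.0406, adjusted p = 0.557 with an estimated correlation). In the mucous list, which did not pass (adjusted p = 0.228), Fxyd4 was at 0.81 and Itln1 at 0.89 (2 of 14, 3 and 1 lower adjusted over the list alone). The macrophage fusion receptor Ocstamp (1.51), the myeloid receptor Tarm1 (1.57) and the heat shock gene Hspa1a (1.74) also passed.

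Club cell genes had a more negative change in KO in 1 of 11 cases (7 adjusted over the list alone), Scgb3a2 at -0.98 (adjusted p = 4.02e-06, adjusted p = 0.146 with an estimated correlation). Ciliated cell genes were lower in this sense in none of 13 over all genes and in 10 adjusted over the list alone (median -0.41, adjusted p = 4.19e-09, adjusted p = 0.146 with an estimated correlation). Alveolar type 2 genes were lower in 2 of 11 (5 adjusted over the list alone), Sftpd at -0.59 and Lamp3 at -0.54 (adjusted p = 3.88e-07, adjusted p = 0.146 with an estimated correlation). Alveolar type 1 genes were lower in none of 10 (0 adjusted over the list alone, adjusted p = 0.0406, adjusted p = 0.702 with an estimated correlation). Alveolar macrophage genes were lower in 1 of 10 (4 adjusted over the list alone), Krt79 at -0.83 (adjusted p = 4.61e-05, adjusted p = 0.146 with an estimated correlation). LXR and fatty acid genes were lower in 1 of 14 (1 adjusted over the list alone), Abcg1 at -0.52 (adjusted p = 0.00153, adjusted p = 0.253 with an estimated correlation). Acute phase genes were lower in 1 of 11 (2 adjusted over the list alone), Orm1 at -1.49 (adjusted p = 0.00381, adjusted p = 0.209 with an estimated correlation). Adipose genes were lower in none of 7 (2 adjusted over the list alone, adjusted p = 0.00421, adjusted p = 0.336 with an estimated correlation). Of 14 clock genes 1 was lower (4 adjusted over the list alone), Dbp at -1.27 (adjusted p = 1.64e-05, adjusted p = 0.209 with an estimated correlation). Apoe (-0.23, adjusted p = 0.372), Lrp8 (0.15, adjusted p = 0.45) and the lipoprotein list (1 of 19 higher, 2 and 2 lower adjusted over the list alone, adjusted p = 0.724) did not pass, although Thbs1, a ligand of the receptor, was at 0.68.

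In total 160 genes differed in their response to HDM, 71 with a positive and 89 with a negative difference (44.4% positive). Of the 27 that differed at least 2-fold, 17 were positive and 10 negative, and of 65 among all probe sets 41 were positive and 24 negative. Without WT saline 2 and 3, which held raised Rnase2a, Ccl24 and Arg1 among saline arrays, 12 genes passed (8 positive, 4 negative) and 30 of 35 single-gene calls ended, with Rnase2a at 2.79, Ccl24 at 3.02 and Arg1 at 2.13. With the clock score as a covariate, which widened the median SE 1.38 times, 1 gene passed, Hal (-3.40, SE 0.48). Rnase2a (2.53, SE 0.84), Ccl24 (2.80, SE 0.76), Arg1 (1.77, SE 0.67) and Tnc (0.79, SE 0.23) then did not. Single arrays moved this count widely. It was 54, 41 and 86 without WT saline 2, 3 and 4, and 300, 59, 325 and 42 without WT HDM 1 to 4. Without KO saline 1 to 4 it was 103, 61, 49 and 45, and without KO HDM 1 to 4 it was 71, 60, 86 and 1019. Of 35 single-gene calls examined, 19 ended without WT HDM 4 and 19 without KO saline 4, 18 without WT saline 3, 17 without WT saline 2 or WT HDM 2, 16 without KO saline 3, 15 without KO saline 2 or KO HDM 2 and 12 without KO HDM 1 or 3. A further 9 ended without WT saline 4, 7 without KO saline 1, 6 without WT saline 1, 2 without WT HDM 1 and 0 without WT HDM 3 or KO HDM 4. List calls that ended were those of the dendritic, mast cell, alveolar type 1 and smooth muscle lists. Of 18 in all, 3 ended without WT HDM 2, 2 without each of WT saline 2, WT saline 3, WT HDM 1, KO saline 2 and KO HDM 1, 2 and 3, and 1 without each of KO saline 1, 3 and 4 and KO HDM 4. The median, mean and test differed in sign for the lipoprotein, T cell and NK cell lists, which did not pass.

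The comparison of genotypes under saline asked how KO and WT lungs differed without allergen. Few genes differed. Nnt, the mitochondrial transhydrogenase gene, was 0.55 higher in KO (SE 0.06, n = 4 per group, limma adjusted p = 0.000619). The mesothelial gene Msln was 0.50 higher (SE 0.06, adjusted p = 0.00272), Gp2, a zymogen granule protein also made by airway epithelium, 1.30 higher (SE 0.23, adjusted p = 0.024), and the lipid transporter Mfsd2a 0.57 higher (SE 0.10, adjusted p = 0.0232). Rnase2a was lower (-2.59, SE 0.49, adjusted p = 0.0322), at 7.63 ± 0.74 (SD) against 10.23 ± 1.37. Without WT saline 2 and 3, where it was at 11.47 and 11.22, the difference was -1.48 and did not pass. Lower too were the interferon-induced genes Gbp2b (-1.39, SE 0.18, adjusted p = 0.00428), Ifi208 (-1.17, SE 0.16, adjusted p = 0.00428) and Ifi44l (-0.91), and Hspa1a (-1.38). The fixed interferon response list, which does not hold these genes, did not pass (0 of 15, 0 adjusted over the list alone, median 0.20, adjusted p = 0.117). Further genes that passed were Abhd12b (0.74), Alkal1 (0.65), Prss30 (1.01), Clca3b (1.03), Cd59a (0.59), Steap4 (0.53), Prmt8 (0.67), Pigp (0.57), Gpr137b (-0.64), Fam107a (-0.62), Dnah8 (-0.77), Adh6b (-0.67) and Sfn (-0.66).

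Cardiac muscle genes, markers of tissue outside the lung parenchyma, were lower in KO as a list (median -0.44, adjusted p = 6.06e-10, adjusted p = 0.249 with an estimated correlation), with 0 of 9 past the test over all genes and 9 adjusted over the list alone. Tnnt2, for example, was at 10.96 ± 0.22 against 11.50 ± 0.23 (-0.54, adjusted p = 0.249). Skeletal muscle genes were lower as a list too (0 of 8, 1 adjusted over the list alone, adjusted p = 0.0191, adjusted p = 0.571 with an estimated correlation). So were smooth muscle (0 of 10, 0 adjusted over the list alone, adjusted p = 0.00172, adjusted p = 0.571 with an estimated correlation) and endothelial genes (0 of 14, 0 adjusted over the list alone, adjusted p = 0.00753, adjusted p = 0.656 with an estimated correlation). Acute phase and complement genes were higher (0 of 11 over all genes, 4 adjusted over the list alone, adjusted p = 1.14e-06, adjusted p = 0.105 with an estimated correlation), with Lbp at 0.43 (adjusted p = 0.0623) and Cfb at 0.65 (adjusted p = 0.0992). The remaining lists that were higher by camera had no member past the test over all genes. These were proliferation (0 of 22, 0 adjusted over the list alone, adjusted p = 0.000247, adjusted p = 0.656 with an estimated correlation) and dendritic cell genes (3 adjusted over the list alone, adjusted p = 0.00013, adjusted p = 0.494 with an estimated correlation). Others were MHC class II (0 adjusted over the list alone, adjusted p = 0.00141, adjusted p = 0.571 with an estimated correlation) and alveolar type 2 genes (2 adjusted over the list alone, adjusted p = 0.00172, adjusted p = 0.52 with an estimated correlation). They also included alveolar macrophage (1 adjusted over the list alone, adjusted p = 0.00349, adjusted p = 0.494 with an estimated correlation), plasma cell (0 adjusted over the list alone, adjusted p = 0.00523, adjusted p = 0.625 with an estimated correlation) and ciliated cell genes (0 adjusted over the list alone, adjusted p = 0.00911, adjusted p = 0.625 with an estimated correlation). Monocyte (0 adjusted over the list alone, adjusted p = 0.0172, adjusted p = 0.625 with an estimated correlation) and club cell genes (0 adjusted over the list alone, adjusted p = 0.0191, adjusted p = 0.571 with an estimated correlation) complete them.

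Among lipoprotein receptors and ligands Vldlr alone was lower past the test (1 of 19, 2 higher and 2 lower adjusted over the list alone, list adjusted p = 0.844). Lrp2 (0.39, adjusted p = 0.0579), Apoe (0.05, adjusted p = 0.957) and Lrp8 (-0.03, adjusted p = 0.973) did not pass, nor did Ccl24 (-0.76, adjusted p = 0.722), Ccl11 (-0.35, adjusted p = 0.714), Ccl17 (0.63, adjusted p = 0.236) and Ccl22 (0.11, adjusted p = 0.958). In all 46 genes differed, 18 higher and 28 lower in KO. Without WT saline 2 and 3 the count was 10, and 18 of 24 single-gene calls ended, that of Vldlr among them. The count was 21 without WT saline 3, and 14, 21, 20 and 16 without KO saline 1 to 4. Of 24 single-gene calls examined, 15 ended without each of KO saline 1 and 4, 13 without KO saline 3, 12 without KO saline 2, 11 without WT saline 3, 7 without WT saline 2, 6 without WT saline 4, 2 without WT saline 1 and at most 1 without any other array. Of 14 list calls, 3 ended without KO saline 4, 2 without KO saline 3, and 1 without each of WT saline 3, WT saline 4, KO saline 1 and KO saline 2. The median, mean and test differed in sign for the LXR, NK cell, neutrophil and matrix lists, none of which passed.

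The comparison of genotypes under HDM asked how lungs with and without the receptor differed after the allergen. Of 22 proliferation genes 17, and of 10 type 2 chemokines and receptors 7, were higher in KO, and 6 of 11 club cell genes were lower. As lists these did not pass with an estimated correlation (adjusted p = 0.25, 0.246 and 0.246). Ccl24 was 7.19-fold higher (2.85, SE 0.41, n = 4 per group, limma adjusted p = 0.000814), at 10.76 ± 1.18 (SD) against 7.91 ± 0.20. Arg1 was 3.83-fold higher (SE 0.38, adjusted p = 0.00515), Mcpt1 5.37-fold (SE 0.61, adjusted p = 0.0171), and the C-type lectin Cd209e 3.42-fold (SE 0.19, adjusted p = 0.000102). For Mcpt1 the groups overlapped. It was at 7.24, 6.83, 9.56 and 9.81 on WT HDM 1 to 4 and between 9.62 and 11.71 on the KO HDM arrays. Hal was lower by the largest amount (-3.07, SE 0.29, adjusted p = 3.47e-05), and Fam107a, a stress-induced actin regulator, was at -1.65 (SE 0.11, adjusted p = 7.84e-07).

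Of 10 type 2 chemokines and receptors 7 were higher (9 adjusted over the list alone), among them Ccl8 (1.27), Ccr8 (0.96), Ccl11 (0.82), Ccl22 (0.82) and Ccl17 (0.67), at a list adjusted p = 3.1e-07 and an adjusted p = 0.246 with an estimated correlation. In the type 2 cytokine list 5 of 15 were higher (8 adjusted over the list alone), with Il13ra2 at 0.99, Il10 at 0.72 and Il4ra at 0.40 (adjusted p = 0.0022, adjusted p = 0.246 with an estimated correlation). Eosinophil genes were higher in 4 of 8 (5 adjusted over the list alone), with Ear6 at 1.51, Alox15 at 0.78 and Prg2 at 0.58 (adjusted p = 0.000398, adjusted p = 0.246 with an estimated correlation). Mucous cell genes were higher in 3 of 14 (4 adjusted over the list alone), with Slc26a4 at 1.03 (adjusted p = 0.00629, adjusted p = 0.246 with an estimated correlation). Alternative macrophage genes were higher in 4 of 16 (8 adjusted over the list alone), with Retnlb at 0.50 and Clec10a at 0.46 (adjusted p = 0.00192, adjusted p = 0.381 with an estimated correlation). Of 16 dendritic cell genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone), with Fscn1 at 0.58 (adjusted p = 6.23e-06, adjusted p = 0.246 with an estimated correlation). Mast cell genes did not pass as a list (4 of 14 higher, 1 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.0511), with Kit at -0.39. In the T cell list, which did not pass (3 of 17 higher, 1 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.376), Icos (0.79), Ctla4 (0.74) and Il2ra (0.66), genes of activated and regulatory T cells, were higher and Cd27 (-0.41) was lower.

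Proliferation genes were higher in 17 of 22 cases (20 adjusted over the list alone), with the topoisomerase Top2a at 0.89, the kinesin Kif11 at 0.84 and Mki67 at 0.78 (list median 0.54, adjusted p = 9.61e-11, adjusted p = 0.25 with an estimated correlation). Matrix genes were higher in 12 of 20 and lower in 1 (16 and 1 adjusted over the list alone), with Timp1 at 1.64, Tnc at 1.11, Eln at 0.83 and Dcn at -0.53 (adjusted p = 5.3e-08, adjusted p = 0.0671 with an estimated correlation). Interferon response genes were higher in 5 of 15 (7 adjusted over the list alone), with Irf7 at 0.82, Usp18 at 0.71 and Oas2 at 0.71 (adjusted p = 0.0146, adjusted p = 0.551 with an estimated correlation). MHC class II genes were higher in 1 of 11 (5 adjusted over the list alone), Cd86 at 0.60 (adjusted p = 0.00486, adjusted p = 0.452 with an estimated correlation). B cell genes were higher in none of 9 (3 adjusted over the list alone, adjusted p = 0.00486, adjusted p = 0.527 with an estimated correlation). Monocyte and interstitial macrophage genes were higher in 1 of 10 (1 adjusted over the list alone, adjusted p = 0.0492, adjusted p = 0.551 with an estimated correlation).

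Club cell genes were lower in 6 of 11 cases (7 adjusted over the list alone), with the abundant secretoglobin Scgb1a1 at -0.94, Scgb3a2 at -0.65 and Cyp2f2 at -0.40 (adjusted p = 0.000398, adjusted p = 0.246 with an estimated correlation). Ciliated cell genes were lower in 4 of 13 (10 adjusted over the list alone), with Tppp3 at -0.54 (adjusted p = 9.12e-07, adjusted p = 0.246 with an estimated correlation). The ciliary gene Sntn outside the list was at -1.20. Alveolar type 2 genes were lower in 5 of 11 (6 adjusted over the list alone), with Lamp3 at -0.34 and Sftpb at -0.31 (adjusted p = 0.000225, adjusted p = 0.246 with an estimated correlation). Alveolar type 1 genes were lower in 2 of 10 (5 adjusted over the list alone, adjusted p = 0.00226, adjusted p = 0.452 with an estimated correlation). Endothelial genes were lower in 5 of 14 (5 adjusted over the list alone), with Kdr at -0.52 and Tek at -0.47 (adjusted p = 0.00241, adjusted p = 0.494 with an estimated correlation). Alveolar macrophage genes were lower in 3 of 10 (4 adjusted over the list alone), with Pparg at -0.40 (adjusted p = 0.00778, adjusted p = 0.25 with an estimated correlation). LXR and fatty acid genes were lower in 6 of 14 (6 adjusted over the list alone), with Elovl6 at -0.39 and Abcg1 at -0.35 (adjusted p = 0.000637, adjusted p = 0.246 with an estimated correlation). Further tissue lists were lower alongside. Cardiac muscle genes were lower in 5 of 9 (6 adjusted over the list alone), with Myh6 at -0.77 (adjusted p = 4.2e-05, adjusted p = 0.246 with an estimated correlation). Adipose genes were lower in 3 of 7 (4 adjusted over the list alone), with Car3 at -1.19 (adjusted p = 0.00982, adjusted p = 0.381 with an estimated correlation). Clock genes differed on the same arrays, 1 of 14 higher and 7 lower (1 and 8 adjusted over the list alone), with Dbp at -1.17, Nr1d1 at -0.69 and Tef at -0.58 (adjusted p = 2.9e-05, adjusted p = 0.246 with an estimated correlation). In the lipoprotein list (adjusted p = 0.611) 3 of 19 were higher and 1 lower (3 and 2 adjusted over the list alone), with Thbs1 at 0.54 and Vldlr lower. Apoe (-0.17, adjusted p = 0.202) and Lrp8 (0.12, adjusted p = 0.252) did not pass.

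Under HDM 2327 genes differed, 1164 higher and 1163 lower in KO, 42 of them at least 2-fold. KO HDM 4 stood apart from the other KO HDM arrays, with Ccl24 at 9.30 against 10.70 to 12.18, and without it 3831 genes differed. The count was 1249 and 1475 without WT HDM 2 and 4, and 968, 1416 and 1119 without KO HDM 1, 2 and 3. With only these 2 groups in the fit it was 390. The clock score as a covariate left 6 genes and widened the median SE 1.82 times. Ccl24 (1.93, SE 0.71), Arg1 (0.86, SE 0.63) and Mcpt1 (0.74, SE 1.0) then did not pass. Of 82 single-gene calls examined, 19 ended without KO HDM 3, 16 without WT HDM 2, 15 without KO HDM 1, 13 without KO HDM 2, 7 without each of WT HDM 1 and WT HDM 4 and at most 2 without any other array. Of 22 list calls, 2 ended without each of KO HDM 3, WT HDM 1 and WT HDM 2, and 1 without each of KO HDM 2, KO HDM 4, WT HDM 4, WT saline 1 and the KO saline arrays. Trim12a and Trim30d, antiviral tripartite motif genes, were lower in KO (-2.72, adjusted p = 0.00322, and -1.97, adjusted p = 0.0164), and on WT saline arrays 1 to 4 Trim12a was at 6.60, 6.45, 9.63 and 8.86. Vldlr at 10.54 and 10.5 on WT saline 1 and 2 argues against a need of receptor loss for low levels. Alleles can segregate in B6129SF2/J mice, a strain cross, but were not tested. The median, mean and test differed in sign for the acute phase, cholesterol synthesis, immediate early, NK cell, skeletal muscle and Vldlr-flanking lists, none of which passed.

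Genes that differed by genotype under saline and under HDM overlapped in part. Higher in both were 4 genes, against 1.051 for independent lists of these lengths, and lower in both were 16, against 1.633, with 0 in opposite directions. Vldlr, Fam107a and Ifi208 are among those lower in both. The count of 20 genes of like direction was 11 without WT saline 3, and 8, 11, 10 and 9 without KO saline 1 to 4. Without WT saline 2 and 3 it was 7, and with the clock score as a covariate 2. Across genes the correlation of the 2 differences was 0.190 (Pearson) and 0.146 (Spearman).

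**Figure D3:**
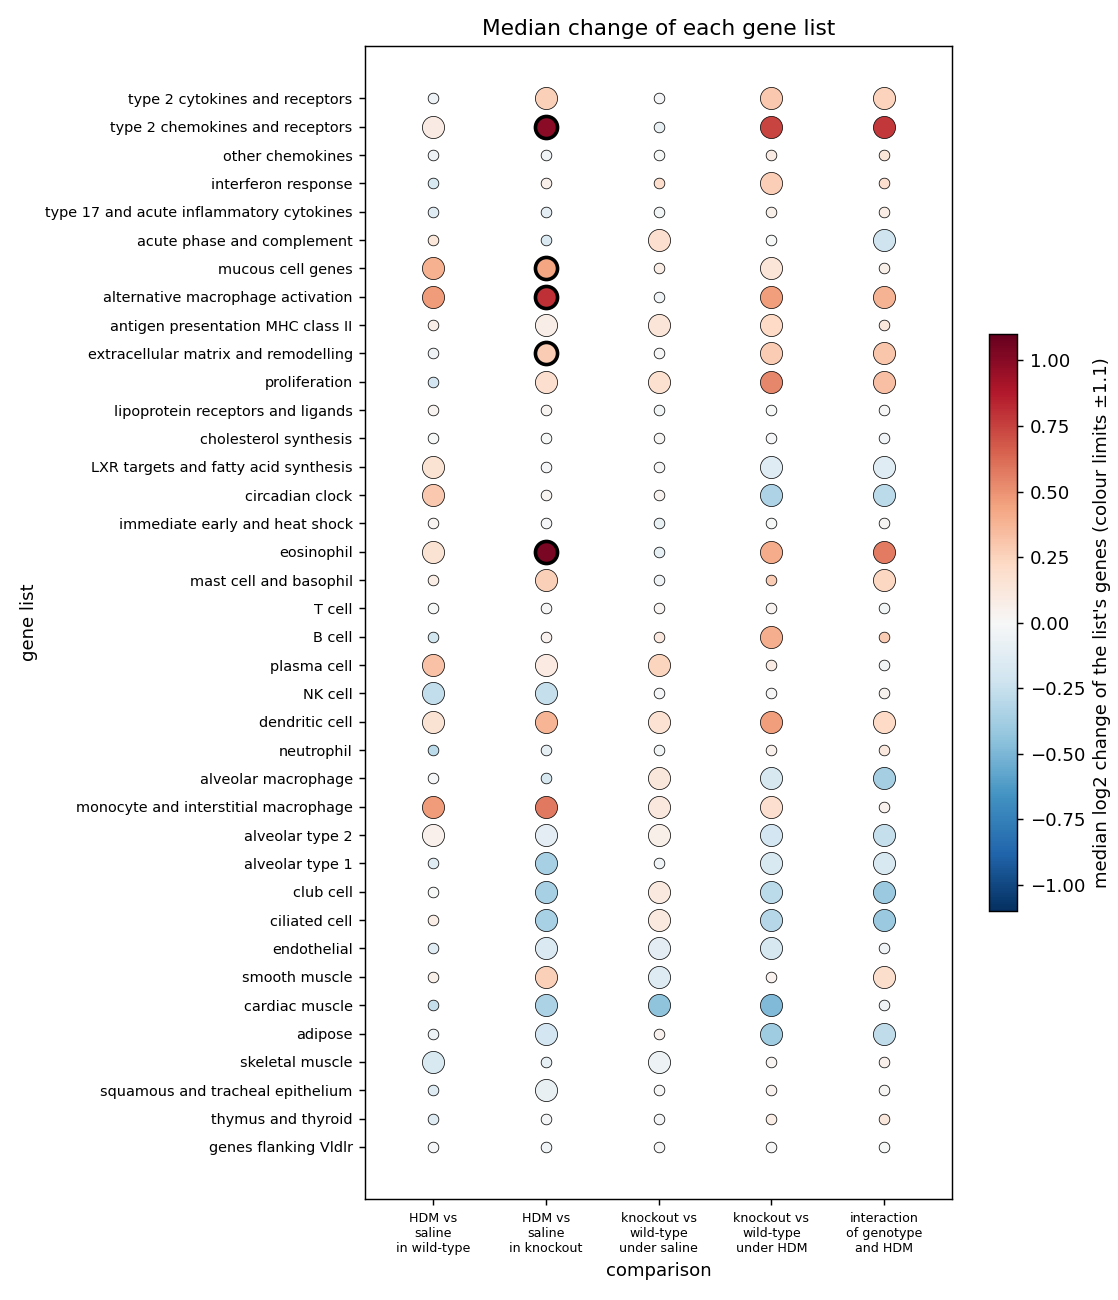
Median log2 change of the tested gene lists (down the side) in the 5 comparisons (across), with the colour giving the median, a large dot for a camera adjusted p under 0.05 with the preset correlation and a thick outline where the adjusted p with an estimated correlation is also under 0.05. Thick outlines appear for 5 lists, all for HDM against saline in KO lungs.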

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

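The tests of an HDM effect on the clock common to both genotypes, of neighbouring genes, of the chromosome of Vldlr and of the single WT saline arrays were chosen after the results they bear on had been seen.

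Differences in HDM effect between genotypes (KO minus WT, limma adjusted p under 0.05) were found for 160 genes. Those with a positive difference included Rnase2a (3.90), Ccl24 (3.61), Arg1 (2.71), Cd209e (2.07), Hspa1a (1.74), Corin (1.66), Tarm1 (1.57), Ocstamp (1.51), Ear6 (1.48), Rnase2b (1.26) and Ccl11 (1.17). Smaller differences in the same direction were those of Ccr8 (1.02), Tnc (1.02), Itln1 (0.89), Fxyd4 (0.81), Eln (0.69), Thbs1 (0.68), Cebpe (0.62) and Col3a1 (0.43). With a negative difference, whatever the size of the change in each genotype, were Hal (-2.48), Il18 (-1.54), Orm1 (-1.49), Clca3b (-1.29), Dbp (-1.27), Cyp2e1 (-1.23), Klhl38 (-1.07), Sntn (-1.07) and Fam107a (-1.03). Below 1 in size were Scgb3a2 (-0.98), Krt79 (-0.83), Sftpd (-0.59), Clec9a (-0.57), Dcn (-0.56), Lamp3 (-0.54) and Abcg1 (-0.52).

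On the WT HDM arrays the clock list stood at a mean of 10.434, against 10.060, 10.079 and 10.106 in the WT saline, KO saline and KO HDM groups. A clock score (8 output genes minus Arntl), chosen after these genes were seen to stand apart, changed by 1.12 in WT and 0.32 in KO, a difference of -0.80 (SE 0.25), and in KO too the HDM arrays (0.77 to 0.91) lay above the saline arrays (0.20 to 0.69). Another time of day of collection for the WT HDM lungs stays open, as 1 of 3 further outputs passed in the direction it needs, Wee1 (0.38, limma adjusted p = 0.0334), while Usp2 (0.25, adjusted p = 0.0537) and Nfil3 (-0.04, adjusted p = 0.833) did not. An HDM effect in both genotypes stays open, as the score restates the pattern, and so does a clock response to HDM that depends on Vldlr, which is untested, with times of collection not given in the sources used here. With the clock score as a covariate, Ccl24 between genotypes under HDM went from 2.85 (SE 0.41) to 1.93 (SE 0.71) and no longer passed, with a smaller difference and a wider error, and Hal, at -4.11 (SE 0.45), still did.

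Between genotypes under saline 46 genes differed, which may reflect alleles of the strain background at loci other than Vldlr. The tables argue against a segment linked to the targeted locus as the source of most of them, as 2.17% (1 of 46, Vldlr itself) lay on its chromosome. Background alleles stay open, as 4 of the 46 had another called gene of another family within 5 gene positions, where 10000 random sets gave a median of 0 and a 95th percentile of 4. The count was 8 with family members kept and 6 with only like-named ones left out, and the pairing of Gp2 with Umod as a family was set after the first count was seen. An effect of the missing receptor stays open too, untested.

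On WT saline 2 and 3 some type 2 genes were high (Chil4 10.59 and 10.20, 8.08 and 9.10 on 1 and 4), not the cytokine list on 3. The tables argue against a swap with a WT HDM array, as Dbp on each WT saline array lay below the lowest WT HDM array by at least 0.92 (SD of the WT HDM group 0.25). RNA of HDM-exposed lungs in WT saline 2 and 3 could give the pattern and stays open only as a mixture. Ccl24 there (9.07 and 9.26) lay above each WT HDM array (7.76 to 8.21), and Hal (9.39 and 9.31) above each KO HDM array (7.84 to 8.12). RNA of a single one of these groups would not give both. On WT saline 2, however, Trim12a (6.45) and Trim30d (6.42) lay below each WT HDM array (9.31 to 9.83 and 8.88 to 9.24). They gave no sign there of RNA from the arrayed WT HDM lungs, which Hal would need. This rests on 2 genes of 1 array. No biological explanation was tested. Of 97 genes that rose at least 2-fold with HDM in KO, 79.4% lay above the highest KO saline array on WT saline 2 and 51.5% on WT saline 3, against 24.7% and 28.9% on WT saline 1 and 4. The share of such RNA needed had a median of 14.3% (quartiles 10.0% and 21.2%) on WT saline 2 and 8.11% (quartiles -0.92% and 14.4%) on WT saline 3, while Chil4 needed 28.3% and 20.4%, Rnase2a 33.7% and 27.9% and Ccl24 20.6% and 25.7%.

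Chance was examined by regrouping the arrays. For HDM in WT, 1 of 35 splits of the 8 arrays into 4 and 4 gave as many genes as the real one (3505), and the highest other split gave 9. For HDM in KO it was 1 of 35 (1763, highest other 376), for genotype under saline 1 of 35 (46, highest other 0), and for genotype under HDM 1 of 35 (2327, highest other 2237). The split with 2237 genes exchanged WT HDM 3 and KO HDM 4, a structure of the HDM arrays besides genotype, while Vldlr and Nnt on both arrays lay with their own genotype. For the interaction 1 of 100 arrangements of the residuals drawn gave as many (160, highest other 3). The share was under 0.05 for both HDM comparisons, genotype under saline and the interaction. It is the smallest that 35 splits or 100 arrangements can give and was not adjusted over the comparisons. It therefore argues against chance without excluding it. For genotype under saline the count also ranged from 14 to 66 when 1 array was left out. For genotype under HDM the share was under 0.05 too, the smallest that 35 splits can give, but the margin over that split is small beside the 968 to 3831 genes found when 1 array was left out, so the count does not set genotype apart from this other structure.

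The gap of a single array to the nearest of its group was large relative to the range of the group in 25 of 692 groups of named genes (3.61%), where chance gives about 1 in 20. The gap divided by the range is given in brackets. It can be high where all 4 arrays lie close together, as for Lbp on KO saline 2 (12.56, nearest 12.58) and Cxcr2 on KO saline 3 (9.59, nearest 9.45). On KO HDM 4, which had 6 of these, Ccl3 (0.855), Tm4sf19 (0.839) and Mcm6 (0.946) were lowest and Hopx (0.858), Nr1d1 (0.851) and Klhl38 (0.838) highest. On KO HDM 3, Dnah8 (0.902) and Thbs1 (0.928) were highest. Among WT HDM arrays Chil4 was lowest on array 1 (0.842) and Gapt on array 2 (0.872). Among WT saline arrays Cd27 was lowest on array 1 (0.894), Lbp lowest on array 3 (0.879), and Sfn (0.854) and Tnnt2 (0.916) highest on array 4. On KO saline 1, Per3 was lowest (0.886) and Retnlb (0.957) and Trim12a (0.855) highest, and on KO saline 2 Gapt (0.850), Lbp (0.902) and Irf7 (0.861) were lowest. Pigp (0.921) and Cxcr2 (0.943) were highest on KO saline 3, and on KO saline 4 Chil3 was lowest (0.913) and Hp (0.955) and Cyp2e1 (0.841) highest.

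Probe sets without a single gene symbol, 13767 in number, also changed. In the fit of all probe sets, those that passed numbered 1496 for HDM in WT, 462 for HDM in KO, 21 for genotype under saline, 722 for genotype under HDM and 16 for the interaction.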

How the results depend on the processing

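The clock covariate, the fry test and leaving out WT saline 2 and 3 together were chosen after the results had been seen, and the other alternatives were planned. Named genes gave 7674 values under the alternatives, of which 6877 kept the direction and the side of the threshold, 750 no longer passed, 32 newly passed and 15 turned direction. Gene lists gave 5427 values, of which 4857 were unchanged in this sense, 248 no longer passed, 89 newly passed and 233 turned direction. Of the results that turned direction, the clock list for HDM in WT, the B cell list for genotype under HDM and the alveolar type 1 list for genotype under HDM and for the interaction had passed, and the others had not. These 4 turned with the clock covariate, the clock list by construction. With the preset correlation 12, 22, 14, 22 and 18 lists had passed for HDM in WT, HDM in KO, genotype under saline, genotype under HDM and the interaction. With an estimated correlation 83 of these calls ended, which left only 5 lists for HDM in KO. By the fry test 43 list calls ended and 6 lists newly passed. The cause was not tested for any change below unless the construction of the alternative gives it. Low signal over background limits dim genes, whose changes an array compresses. With the variance trend or the mean of a gene's probe sets no direction turned and no count moved over 1.5 times. The planned covariate for sex was not run.

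Counts of changed genes moved over 1.5 times as follows. Array weights gave 2938 genes for HDM in KO, 110 for genotype under saline and 680 for the interaction, with agreements of 1016 (HDM effects) and 42 (genotype effects). Only the 2 groups compared in the fit gave 98 genes for genotype under saline and 390 for genotype under HDM. An added 2-fold threshold left 51, 121, 9, 42 and 27 genes in the 5 comparisons (in the order above) and agreements of 33 and 1, by construction. All probe sets gave 65 genes for the interaction, with more tests to adjust for. The filter at the 50th percentile gave 27 genes for genotype under saline and an agreement of 13, with fewer genes tested. The clock covariate left 43 genes for HDM in WT, 6 for genotype under HDM and 1 for the interaction, and agreements of 37 and 2. It widened the median SE 2.12, 1.82 and 1.38 times, and 94.5%, 97.7% and 100% of the genes called there kept their direction. Clca1 for HDM in WT went from 2.64 (SE 0.46) to 3.87 (SE 0.94). Without WT saline 2 and 3 the counts were 1057 for HDM in WT, 10 for genotype under saline and 12 for the interaction, with agreements of 320 and 7 and fewer arrays.

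Replicate numbers recur in each group. Of 24 pairs of same-numbered arrays 7 had a correlation of deviations over 0.1 (-0.276 to 0.333, median 0.042), and 6 of 16 arrays were closest to an array of their own number, so the numbers were not taken to pair the arrays. With the replicate block the interaction had 258 genes against 160, and Mcpt1, Mcpt2 and Il13ra2 newly passed there. Thymus (-0.018) then turned for genotype under saline. NK cell (0.006) turned for genotype under HDM. T cell (-0.033) and NK cell (0.037) turned for the interaction.

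Leaving out 1 array at a time gave 1960 (without WT HDM 4) to 3799 (without KO HDM 4) genes for HDM in WT, 1034 (without KO HDM 3) to 2673 (without KO HDM 4) for HDM in KO and 14 (without KO saline 1) to 66 (without WT HDM 2) for genotype under saline. Genotype under HDM gave 968 (without KO HDM 1) to 3831 (without KO HDM 4) and the interaction 41 (without WT saline 3) to 1019 (without KO HDM 4). Agreements ranged from 419 (without KO saline 2) to 749 (without KO HDM 4) for HDM effects and from 8 (without KO saline 1) to 26 (without KO HDM 4) for genotype effects. Without at least 1 array the direction of the following turned, given with the lowest and highest log2 change or list median. Vldlr (-0.160 to 0.056), other chemokines (-0.086 to -0.019), immediate early (-0.011 to 0.050), B cell (-0.289 to -0.066) and adipose (-0.107 to 0.005) turned for HDM in WT. Apoe (-0.034 to 0.058), other chemokines (-0.061 to -0.028), interferon response (-0.038 to 0.195), type 17 cytokines (-0.128 to -0.055), cholesterol synthesis (-0.062 to 0.029) and LXR (-0.038 to 0.020) turned for HDM in KO. Clock (-0.036 to 0.057), B cell (-0.120 to 0.135), thymus (-0.053 to 0.024) and Vldlr-flanking (-0.048 to -0.021) turned there too. Apoe (-0.005 to 0.143), type 2 cytokines (-0.055 to 0.022), type 2 chemokines (-0.106 to -0.030), other chemokines (-0.042 to 0.028), matrix (-0.018 to 0.032) and lipoprotein (-0.044 to 0.004) turned for genotype under saline. LXR (-0.048 to 0.028), clock (0.010 to 0.043), NK cell (-0.096 to 0.122), neutrophil (-0.082 to -0.005), adipose (-0.018 to 0.113) and squamous (-0.016 to 0.028) turned there too. Thymus (-0.042 to 0.019) and Vldlr-flanking (-0.008 to 0.015) turned there too. Type 17 cytokines (-0.027 to 0.122), acute phase (-0.063 to 0.014), cholesterol synthesis (-0.018 to 0.032), plasma cell (-0.046 to 0.255), NK cell (-0.054 to 0.067) and smooth muscle (0.007 to 0.078) turned for genotype under HDM. Skeletal (-0.027 to 0.057) turned there too. Ccl17 (-0.113 to 0.221), MHC class II (0.043 to 0.195), T cell (-0.048 to 0.023), plasma cell (-0.131 to 0.046), NK cell (-0.035 to 0.126) and monocyte (-0.069 to 0.185) turned for the interaction. Cardiac (-0.161 to 0.063) and squamous (-0.009 to 0.045) turned there too.

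Other alternatives turned the direction of a list's test or a gene as follows, with the list's median or the log2 change in brackets. A median can keep its sign where the test turns. After quantile normalization, matrix (-0.077), cholesterol synthesis (-0.046), immediate early (0.011) and thymus (-0.058) turned for HDM in WT. Matrix (-0.004), LXR (-0.006) and thymus (0.002) turned for genotype under saline. Acute phase (0.009) and cholesterol synthesis (-0.010) turned for genotype under HDM. T cell (-0.026), cardiac (-0.033) and squamous (-0.039) turned for the interaction. At the same median, Vldlr-flanking (-0.041) turned for HDM in KO. Neutrophil (-0.014) turned for genotype under saline. T cell (-0.058) and squamous (-0.014) turned for the interaction. Above the 25th percentile, immediate early (0.020) turned for HDM in WT. Other chemokines (-0.049) turned for HDM in KO. Other chemokines (-0.005) and LXR (0.007) turned for genotype under saline. Type 17 cytokines (0.037), cholesterol synthesis (-0.009) and NK cell (0.040) turned for genotype under HDM. T cell (-0.033) and NK cell (0.085) turned for the interaction. Above the 50th percentile, matrix (-0.045), cholesterol synthesis (-0.002) and immediate early (0.096) turned for HDM in WT. Interferon response (0.038), LXR (-0.015), clock (0.019) and neutrophil (0.125) turned for HDM in KO. Type 2 cytokines (-0.025), other chemokines (-0.001), matrix (0.003), lipoprotein (0.019), LXR (0.007), clock (0.023) and neutrophil (-0.128) turned for genotype under saline. Acute phase (-0.034) and cholesterol synthesis (-0.009) turned for genotype under HDM. Mucous (-0.106) and T cell (-0.039) turned for the interaction.

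With array weights, other chemokines (-0.026) and adipose (-0.075) turned for HDM in WT. Cholesterol synthesis (0.031) and Vldlr-flanking (-0.026) turned for HDM in KO. Matrix (-0.002), LXR (0.001) and thymus (-0.009) turned for genotype under saline. Cholesterol synthesis (0.010) turned for genotype under HDM. T cell (-0.018) and squamous (-0.013) turned for the interaction. With only the 2 groups compared in the fit, cholesterol synthesis (-0.007) turned for HDM in KO. LXR (0.007) and neutrophil (-0.026) turned for genotype under saline. NK cell (0.006) turned for genotype under HDM. By the fry test, matrix (-0.045), cholesterol synthesis (-0.002), immediate early (0.020), adipose (-0.057) and Vldlr-flanking (-0.012) turned for HDM in WT. Other chemokines (-0.049) turned for HDM in KO. LXR (0.007) and neutrophil (-0.026) turned for genotype under saline. Acute phase (-0.006), cholesterol synthesis (-0.009), NK cell (0.006) and skeletal (0.018) turned for genotype under HDM. Lipoprotein (0.001), T cell (-0.033), NK cell (0.037) and cardiac (-0.049) turned for the interaction.

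With the clock covariate, Ccl24 (0.472), Lrp8 (0.10), other chemokines (0.082), type 17 cytokines (0.075), proliferation (0.056), cholesterol synthesis (-0.121), clock (-0.089) and B cell (0.366) turned for HDM in WT. Alveolar macrophage (-0.245), club (-0.193), ciliated (-0.341), adipose (-0.501), thymus (-0.023) and Vldlr-flanking (-0.042) turned there too. Type 17 cytokines (-0.045) and clock (-0.105) turned for HDM in KO. Neutrophil (-0.048) turned for genotype under saline. Lrp8 (-0.045), other chemokines (-0.122), type 17 cytokines (-0.056), acute phase (0.055), cholesterol synthesis (0.074), mast cell (0.104), T cell (-0.101) and B cell (0.021) turned for genotype under HDM. Plasma cell (-0.355), alveolar type 1 (-0.012) and Vldlr-flanking (0.014) turned there too. Other chemokines (0.015), type 17 cytokines (-0.020), MHC class II (0.002), cholesterol synthesis (0.023), immediate early (0.016), B cell (-0.015), monocyte (-0.170) and alveolar type 1 (0.001) turned for the interaction. Endothelial (0.048), cardiac (0.178), skeletal (-0.033), squamous (-0.004) and Vldlr-flanking (0.018) turned there too. Without WT saline 2 and 3, cholesterol synthesis (-0.048) turned for HDM in WT. Lrp8 (0.026), type 2 cytokines (-0.047), type 2 chemokines (-0.060), other chemokines (0.024), interferon response (0.072), alternative macrophage (0.017), cholesterol synthesis (-0.032) and LXR (-0.032) turned for genotype under saline. NK cell (-0.011), neutrophil (-0.064) and thymus (0.008) turned there too. Ccl17 (-0.288), MHC class II (0.073), cholesterol synthesis (0.028), NK cell (0.064), cardiac (0.10) and squamous (-0.013) turned for the interaction.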

Other observations

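The lists below were fixed in advance, and Trim12a and Trim30d were singled out after their values were seen.

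Neutrophil genes moved in both directions with HDM. In WT 1 of 14 rose and 5 fell, and in KO 1 rose and 4 fell (1 and 7, and 3 and 5, adjusted over the list alone), while the list did not pass (limma camera adjusted p = 0.0648 and 0.266, with a median of -0.300 and -0.098). The granule gene Ltf fell by 1.18 and the collagenase Mmp8 fell by 1.03 in KO, whereas Retnlg, a resistin-like gene of neutrophils, rose by 1.59 in WT and by 2.14 in KO. Between genotypes under HDM the neutrophil receptors Cxcr2 (0.99) and Il1r2 (0.98) were higher in KO. Of 22 other chemokines 3 rose and 4 fell in WT and 5 rose and 4 fell in KO (3 and 4, and 7 and 5, adjusted over the list alone), and the list did not pass (adjusted p = 0.636 and 0.813). Ccl9 and Ccl3 rose in KO by 1.68 and 1.89, Ccl19 fell by 1.09 in WT, and Ccl20, an attractant of Ccr6-bearing cells, fell by 0.96 in WT.

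The remaining lists passed in none of the 5 comparisons. For HDM in WT and in KO the camera adjusted p was 0.259 and 0.702 for type 17 cytokines, 0.593 and 0.917 for cholesterol synthesis, 0.724 and 0.266 for immediate early and heat shock genes, 0.542 and 0.57 for T cells, 0.494 and 0.676 for thymus and thyroid, and 0.239 and 0.934 for the 116 genes flanking Vldlr. The erythroid list, with 2 measured genes (median -0.288 in WT and -0.512 in KO), and the sex list, with 4 (median -0.072 and -0.041), were too short to test.

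On single arrays Trim12a and Trim30d took widely separate levels within the WT saline group. Trim30d was at 6.60 and 6.42 on WT saline 1 and 2 and at 9.42 and 9.22 on WT saline 3 and 4, between 8.88 and 9.24 on the WT HDM arrays and between 6.53 and 7.24 on the KO arrays. Trim12a was at 6.60, 6.45, 9.63 and 8.86 on WT saline 1 to 4, between 9.31 and 9.83 on the WT HDM arrays and between 6.46 and 7.16 on the KO arrays.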
